A study of Drosophila melanogaster with 12 samples.

How the data were processed

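Chromatin immunoprecipitation followed by sequencing was used in Kc167 cells, a Drosophila melanogaster line derived from embryos and labelled as female. Per the labels' protocols, cells received either no RNA (mock) or 12 µg of double-stranded RNA against CP190 (dsCP190) by nucleofection and were grown for 6 days. Chromatin was fragmented to 200 to 500 bp and precipitated with 5 µg of antibody against CP190 or against CLAMP. The series holds 12 samples, of which 8 are immunoprecipitations and 4 are inputs, with 2 replicates per group. The inputs were not used here. The design text of the series speaks of CLAMP knockdown, whereas every sample label and the series title name CP190 knockdown; the sample labels were followed.

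Each immunoprecipitation had 1 peak list in the narrowPeak layout, called per sample and not on pooled replicates. Per the submitters' processing notes, the build was dm6 and the tools were cutadapt 1.16, Bowtie2 2.3.4.1, Picard 2.18.9, MACS2 2.1.1.20160309 and deepTools 3.0.2, listed without roles. The control library and the calling parameters are not given in the sources used here. For each peak the authors deposited a score, a fold enrichment, a −log10 p and a −log10 q. The score is 10 times the −log10 q without its decimals, as the values show. The lowest −log10 q on the chromosome arms lay between 1.30 and 2.01 in the lists, so the threshold behind each list is not known from the values, and alternatives with a −log10 q of at least 3 and of at least 10 put all lists on 1 threshold. The deposited fold enrichment and −log10 p are values of single peaks made by the authors' peak caller. They were used to rank and describe peaks within a list and, as set out below, to recover the fragment numbers behind them.

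Peaks were distinct intervals on chromosome arms 2L, 2R, 3L, 3R, 4 and X. Regions were the union of peaks of an antibody's 4 libraries that overlapped by at least 1 bp. A region called in both mock libraries is termed reproducible. Of these, lost regions were called in neither dsCP190 library and kept regions in both. Kept refers to the call only and not to unchanged enrichment. Gained regions were called in both dsCP190 libraries and in neither mock library. For the overlap of the proteins, regions were built from the libraries of 1 treatment only, which gives slightly different totals. Coordinates are 1-based on dm6.

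Peak numbers were compared by a two-sided exact permutation test. With 2 libraries against 2, its smallest p is 0.333. Overlap was set against 1000 random placements of the CP190 regions within their chromosome arm, and over genes by a two-sided Fisher's exact test. Retention is the share of reproducible mock regions still called after dsCP190. It was compared by a Mantel-Haenszel odds ratio within 5 strata (quintiles of the mean within-list rank of mock fold enrichment), in each dsCP190 library separately. A difference was called where both 95% intervals lay on the same side of 1. Shares carry 95% Wilson intervals, which cover counting error only. Regions and genes are not biological replicates, so these intervals and Fisher p-values describe these libraries. The labels do not say whether replicates came from separate cultures. Permutation p-values between libraries thus measure only the spread between these samples, which may be technical. Fisher and random-placement p-values hold no spread between libraries.

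Genes came from a table of NCBI RefSeq genes on Release 6 of the assembly, the same build as the peak lists. The table gives gene starts and ends without strand or exons. The planned test at promoters therefore became a test at gene ends: a gene is bound when a region's mean mock summit lies within 500 bp of either annotated end, which includes 3' ends. Exons and introns were not separated, and the planned motif search at summits was not run. Location was taken against the ends of 13922 protein-coding genes and compared with 20000 random positions. The 12 gene lists were tested among 15881 protein-coding and lncRNA genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists of an antibody. Of 168 listed symbols, 162 matched the table, apart from ribosomal protein and histone genes, which were taken by the start of their symbol. A bound gene counts as lost when every region at its ends was lost. Neighbouring genes can share a region, so genes are not independent.

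Named genes followed a fixed rule. Per antibody, regions at gene ends were ranked by mock fold enrichment, and the first 12 lost and the first 8 kept with a symbol other than a CG or CR number were named, with the first 5 gained ranked in the dsCP190 lists. The first 10 genes with both proteins in mock cells, up to 4 bound members per gene list, and Cp190 and Clamp were added. A gene that this rule selects is not reported here. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

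Sequencing depth was recovered from the peak values. At a given peak, fold enrichment and −log10 p fix the summit pileup and the local background if fold is the ratio of pileup plus 1 to background plus 1 and p is a Poisson upper tail. This form was assumed and checked on the values. Among peaks with −log10 p under 300, at least 99.9% of each list gave a whole pileup within a relative tolerance of 0.0001 of −log10 p. To ask what lower depth alone would do, mock summit pileups were thinned to the depth of another library, with the ratio of backgrounds at shared summits as the scale, and tested against that library's lowest −log10 p. Peaks with −log10 p of 300 or more were counted as passing.

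On simulated regions in which both the partner and retention followed peak strength, 200 draws with a true odds ratio of 1 gave a mean within-strata odds ratio of 1.04 for both antibodies, against 1.85 for CP190 and 1.86 for CLAMP without strata. The 95% interval held the true value in 92.0% of draws for CP190 and 94.0% for CLAMP. A single interval thus excluded 1 in 8% and 6% of these draws, and in all draws with a true odds ratio of 2 or 4. The rule that asks for both libraries was not simulated. In the draws, on 7669 CP190 and 4471 CLAMP regions, the share with the partner fell steadily from strong to weak regions. In the data, CP190 lay at 357 of 731 CLAMP regions in the strongest quintile. In the middle quintile it was 249 of 731, and in the weakest 380 of 730. The simulated error rates therefore need not hold for the CLAMP comparison. Alternatives tried were stricter q thresholds, equal list lengths within a treatment, other overlap rules, other strata and other gene-end windows. All sequences, each replicate left out in turn, and a replicate block were tried too. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.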

Results

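Binding of CP190 and CLAMP was mapped in Kc167 cells with and without dsRNA against CP190. CP190 is a zinc-finger protein of Drosophila chromatin insulators, and CLAMP is a zinc-finger protein that binds GA-rich DNA and takes part in male dosage compensation. The 8 peak lists fell into 4 groups of 2 replicates. On the chromosome arms, CP190 lists held 7669 and 7964 peaks in mock cells and 2047 and 3138 in dsCP190 cells. CLAMP lists held 4471 and 4514 peaks in mock cells and 2468 and 901 in dsCP190 cells. Read totals were not used here, but the ratio of local backgrounds at shared summits gives the relative depth. For CP190, dsCP190 replicate 1 had 0.894 of the depth of mock replicate 1 and 0.651 of that of mock replicate 2, and dsCP190 replicate 2 had 0.714 and 0.522. For CLAMP these ratios were 0.369 and 0.447 in dsCP190 replicate 1 and 0.352 and 0.427 in replicate 2, so the CLAMP comparison set deeper mock libraries against shallower dsCP190 libraries.

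The CP190 immunoprecipitations, made against the targeted protein, had fewer peaks in both dsCP190 libraries than in either mock library. No measure of CP190 protein or RNA was used here, so the counts do not by themselves show a knockdown. CP190 was called at the ends of Set2, a histone H3 lysine 36 methyltransferase, and Ubx, a Hox gene of the bithorax complex, in both mock libraries and in neither dsCP190 library. The same held for Mmp2, a matrix metalloproteinase, Gr98d, a gustatory receptor, SLO2, a potassium channel, and Cpr62Ba, a cuticle protein, and for Mur11Da, MME1, Spn77Ba, scaf, SP1173 and Boot. CP190 was still called in all 4 libraries at bcd, the anterior determinant of the embryo, betaTub60D, a beta-tubulin, Sar1, a GTPase of vesicle transport, and at Atet, lov, Sytbeta, PhKgamma and fal. At the Cp190 gene itself, the CP190 region on 3R from 15274696 to 15275748 was called in both mock libraries (fold enrichment 7.74 and 7.96) and in dsCP190 replicate 2 only.

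Mean CP190 peak number was 7816.5 ± 209 (SD, n = 2) in mock cells and 2592.5 ± 771 (SD, n = 2) in dsCP190 cells, a ratio of 0.332. The two-sided exact permutation test gave p = 0.333, the smallest p that n = 2 against 2 allows. Of 7356 reproducible CP190 regions, 4295 (58.4%) were lost and 1661 (22.6%) were kept. The other pairings of the 4 libraries gave at most 9 regions in place of those lost. Each pairing needs a call in a dsCP190 library and none in a mock library. Short dsCP190 lists alone keep such counts low, so they are no chance level for loss. Of the reproducible regions, 1280 were called in dsCP190 replicate 2 but not 1, and 120 the other way. Another 24 regions were gained, among them regions at Vsx1, E5 and caup, which encode homeodomain proteins, at Psc, a Polycomb group gene, and at noc. The lost Set2 region spanned X from 13420684 to 13421771, with mock fold enrichments of 43.7 and 36.8, and the lost Ubx region spanned 3R from 16655340 to 16656975, with 28.0 and 24.1. Replicate 1 of dsCP190 retained 24.2% of the mock regions and replicate 2 retained 40.0%. Weak regions were retained least: in replicate 1 the share was 74.0% in the strongest quintile and 2.92% in the weakest, and in replicate 2 it was 89.8% and 2.45%. With a −log10 q of at least 10 the ratio of peak numbers was 0.221. The gained count was then 5. It was 63 without dsCP190 replicate 1 and 186 without dsCP190 replicate 2, where a gained region needs a call in only 1 dsCP190 library. These higher counts follow from the looser definition.

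**Figure D1:**
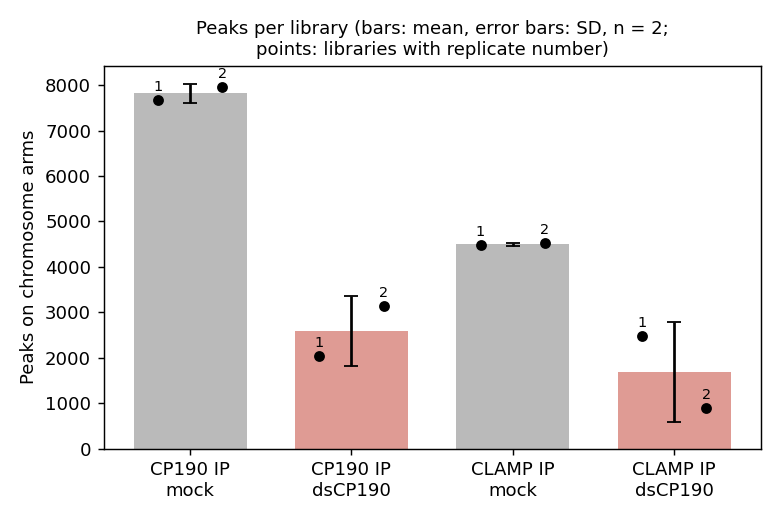
Peaks on the chromosome arms (vertical axis) for each antibody and treatment, with bars for means with SD (n = 2) and points for libraries with their replicate number. CP190 lists ran from 7669 to 7964 peaks in mock and from 2047 to 3138 in dsCP190 cells, and CLAMP lists from 4471 to 4514 and from 901 to 2468.

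CLAMP peak lists were also shorter in both dsCP190 libraries. CLAMP was called in both mock libraries and in neither dsCP190 library at zormin, a titin-like muscle gene, Sf3a1 and SmD1, which encode splicing factors, hth, a homeodomain cofactor of Hox proteins, SK, a potassium channel, and Tie, a receptor tyrosine kinase. Nost, GstT4, Hexo2 and Aldh also lost their call, as did a histone gene, His1:CG33804, whose many near-identical copies make its value uncertain. One end of NFAT, on X from 13663948 to 13664526, lost its CLAMP region, while a region at its other end, from 13624267 to 13625743, was called in all 4 libraries. The 8 kept regions named by the ranking lay at Dr, caup and Lim1, which encode homeodomain proteins, at mid, a T-box gene, at SoxN, a Sox gene, at Rac2, at nej, which encodes the acetyltransferase CBP, and at Glyp, glycogen phosphorylase. At Clamp itself, the region on 2L from 22168249 to 22169488 was called in all 4 libraries, with mock fold enrichments of 11.9 and 13.4.

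Mean CLAMP peak number was 4492.5 ± 30.4 (SD, n = 2) in mock cells and 1684.5 ± 1108 (SD, n = 2) in dsCP190 cells, a ratio of 0.375. The two-sided exact permutation test again gave p = 0.333 with n = 2 against 2, the smallest it can give. Of 3654 reproducible CLAMP regions, 1461 (40.0%) were lost and 801 (21.9%) were kept, while 2 regions were gained. The other pairings of the 4 libraries gave at most 29 regions in place of those lost, which for the same reason is no chance level for loss. Of the reproducible CLAMP regions, 1387 were called in dsCP190 replicate 1 but not 2, and 5 the other way. The dsCP190 replicates differed from each other: replicate 1 retained 59.9% of mock regions and replicate 2 retained 22.1%, the opposite order to that for CP190. The mock lists shared 71.4% of the CLAMP regions called in either, against 90.4% for CP190. The lost count was 2849 without dsCP190 replicate 1, 2255 without mock replicate 1 and 2217 without mock replicate 2. Without dsCP190 replicate 1 the ratio of peak numbers was 0.201 and 15 regions were gained, and without dsCP190 replicate 2 the gained count was 45. Leaving out a library loosens the definitions of lost and gained, so these higher counts follow from the definitions.

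In mock cells, CLAMP and CP190 were called at many of the same places. Among the 10 genes with the highest ranks for both were nej, dx, a regulator of Notch signalling, dco, a casein kinase gene, eIF4E1, which encodes a translation initiation factor, Uba1, the ubiquitin-activating enzyme, and pzg, which encodes a zinc-finger protein. Dlg5, nsl1, Glyp and NFAT completed the set. At dco, the CLAMP region on 3R from 31059380 to 31061725 had mock fold enrichments of 17.3 and 14.4, and the CP190 region there had 33.0 and 22.5. All 10 CLAMP regions and the CP190 regions at them were also called in both dsCP190 libraries.

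Of 3655 CLAMP regions in mock cells, 1545 (42.3%, Wilson interval 40.7 to 43.9) overlapped a CP190 region. Random placement gave a mean of 9.63% and a maximum of 11.6% (permutation p = 0.000999, the smallest that 1000 placements can give). The placements were uniform along the arm and did not keep the share of regions at gene ends. They cannot separate overlap of the 2 proteins from a shared preference for gene ends. Of 7359 CP190 regions, 1516 (20.6%) overlapped a CLAMP region. At gene ends, 1259 of the 1662 CLAMP-bound protein-coding genes also had CP190 (75.8%), against 44.4% of the others (odds ratio 3.91, Fisher's exact p = 9.48e-132). Summits were often apart: the median distance over 1581 overlapping pairs was 225 bp, and 34.0% lay within 100 bp. The overlap was 20.5% when each peak had to share 50% of its length and 14.4% when summits had to lie within 100 bp.

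In dsCP190 cells, both proteins were still called at pzg, Dlg5, nej, dx, nsl1, Glyp, dco, NFAT, Uba1 and eIF4E1. A call does not mean unchanged enrichment. At nsl1, CP190 fold enrichment was 27.6 and 24.1 in mock and 3.33 and 6.18 in dsCP190 replicates 1 and 2. At dco it was 33.0 and 22.5 in mock and 17.6 and 26.3 in dsCP190 replicates. Differences in fold between libraries were not tested. Of 827 CLAMP regions called in both dsCP190 libraries, 165 (20.0%, Wilson interval 17.4 to 22.8) overlapped a CP190 region, against a mean of 2.22% and a maximum of 3.99% after random placement (permutation p = 0.000999, the smallest possible). Of the 300 protein-coding genes with CLAMP, 97 also had CP190 (32.3%), against 12.3% of the others (odds ratio 3.39, Fisher's exact p = 4.24e-19). Random placement was again uniform along the arm, so the limit given for mock cells holds here too. The lists differ in length from those of mock cells, and the difference in overlap between treatments was not tested. With every dsCP190 list cut to its 901 strongest peaks, the length of the shortest, the overlap was 7.64%. This does not equal the length of the mock lists. With a −log10 q of at least 10 the overlap was 13.1%. When each peak had to share 50% of its length it was 8.21%, and with summits within 100 bp it was 4.62%.

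Whether CLAMP was lost where CP190 had been present was asked among the reproducible CLAMP regions. Regions that overlapped CP190, such as those at Dlg5, nsl1 and eIF4E1, were retained in 62.9% of 1545 cases in dsCP190 replicate 1, against 57.7% of 2109 regions without CP190. In replicate 2 the shares were 22.8% and 21.5%. Within strength quintiles, the odds ratio was 1.76 (95% interval 1.45 to 2.13) in replicate 1 and 0.766 (0.603 to 0.974) in replicate 2. The directions were opposite, so no difference was called. In the middle quintile of replicate 1, 74.3% of regions with CP190 and 55.8% of those without were retained. In replicate 2 these were 2.01% and 3.32%. With summits required to lie within 100 bp the replicate 1 odds ratio was 0.856, and without strata the replicate 2 odds ratio was 1.08.

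CP190 calls were retained more often where CLAMP had been called. At nej, dco and Uba1, where both proteins were present in mock cells, CP190 was called in all 4 libraries. These genes were named for high ranks, and strong regions were often retained without CLAMP too. In the strongest quintile of dsCP190 replicate 1, the share was 90.1% with CLAMP and 67.8% without. In replicate 2 it was 98.0% and 86.7%. In dsCP190 replicate 1, CP190 was retained at 45.1% of 1515 regions with CLAMP and at 18.8% of 5841 regions without. In replicate 2 it was retained at 61.5% and 34.4%. The odds ratio within strength quintiles was 4.26 (95% interval 3.60 to 5.03) in replicate 1 and 3.81 (3.19 to 4.54) in replicate 2, so the difference was called. Among the weakest CP190 regions of replicate 1, 18.1% of 204 with CLAMP were retained, against 0.474% of 1267 without. When each peak had to share 50% of its length, the odds ratios were 2.60 and 1.92, and with summits within 100 bp they were 2.58 and 2.43, with both intervals above 1 in each case.

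**Figure D2:**
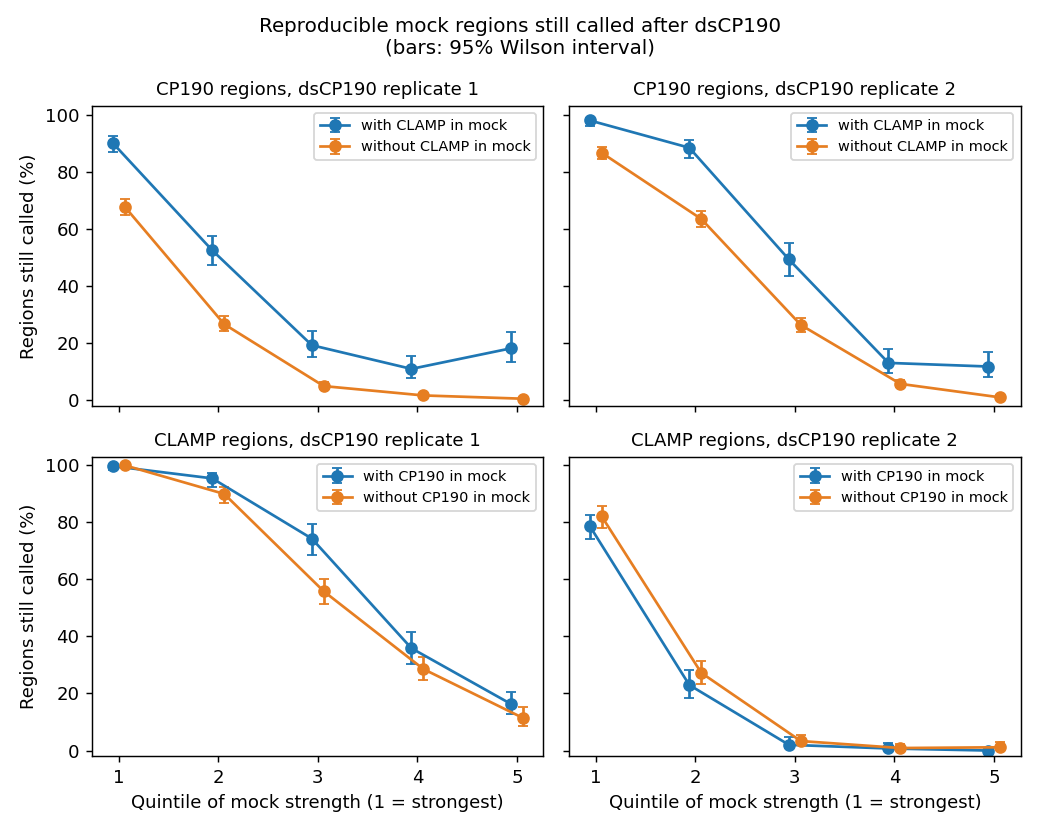
Share of reproducible mock regions still called after dsCP190 (vertical axis, %) by quintile of mock strength (horizontal axis, 1 is strongest), with antibodies in rows, dsCP190 replicates in columns, colours for regions with and without the other protein in mock cells, and 95% Wilson intervals as bars. CP190 regions with CLAMP lie above those without in every quintile of both replicates.

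The location of CP190 and CLAMP regions was set against that of random positions. At protein-coding gene ends lay 62.1% of reproducible CP190 regions and 34.3% of CLAMP regions, against 15.1% of random positions. Inside genes, away from their ends, lay 24.2% of CP190 and 52.9% of CLAMP regions, against 56.7% of random positions, and between genes lay 13.6%, 12.8% and 28.1%. CP190 at gene ends was retained more often than elsewhere. The regions at bcd, lov and Sar1 were named because they were kept at gene ends, so they are no evidence for this. The share was 27.0% at gene ends against 19.6% elsewhere in dsCP190 replicate 1, and 45.7% against 30.6% in replicate 2. The odds ratios within strength quintiles were 1.94 (95% interval 1.67 to 2.25) and 3.07 (2.64 to 3.56). The weakest quintile went the other way, with 1.69% retained at gene ends against 4.28% elsewhere in replicate 1 and 1.95% against 3.00% in replicate 2. For CLAMP the odds ratios were 1.60 (1.31 to 1.95) and 0.878 (0.680 to 1.13), and no difference was called. Gene ends held 56.0% of lost and 69.7% of kept CP190 regions, and 35.6% of lost and 31.5% of kept CLAMP regions. Without strata the CP190 odds ratio in replicate 2 was 1.91, and the CLAMP odds ratio in replicate 1 was 0.916.

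The X chromosome was compared because CLAMP acts at X-linked sites in males. It held CP190 regions at roX1 and roX2, the noncoding RNAs of the dosage compensation complex, and at Sxl, the sex-determination switch, and at each of these CP190 was called in all 4 libraries. For CP190 the odds ratio of retention on X against autosomes was 1.03 in dsCP190 replicate 1 and 0.946 in replicate 2. For CLAMP it was 0.945 and 1.27. All 4 of the 95% intervals included 1, the widest being 0.976 to 1.66, and no difference was called. X held 18.1% of lost and 20.5% of kept CP190 regions, and 25.3% of lost and 28.2% of kept CLAMP regions.

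**Figure D3:**
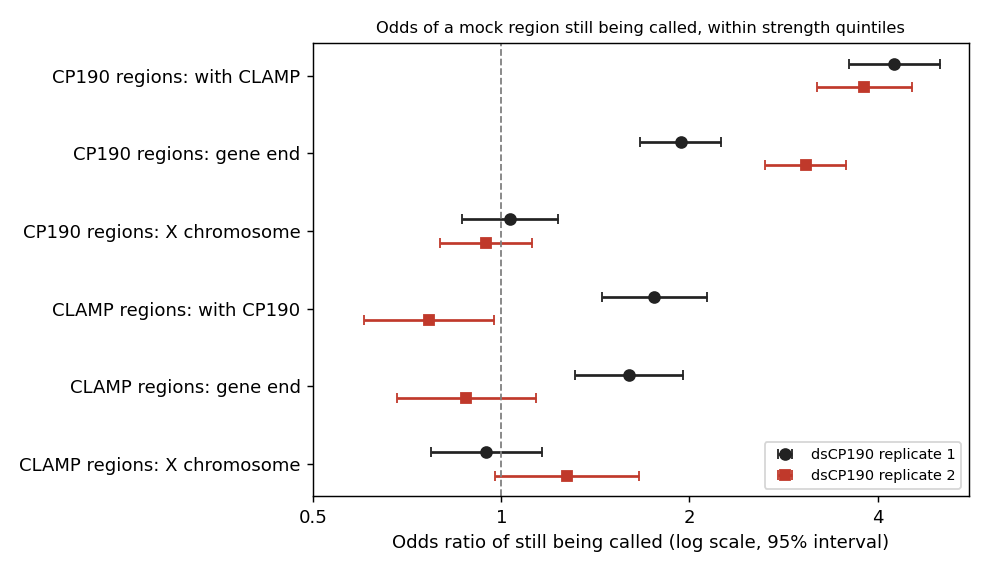
Odds ratios of a reproducible mock region still being called after dsCP190 (horizontal axis, log scale) for overlap with the other protein, gene ends and X, within strength quintiles, with points for the dsCP190 replicates and their 95% intervals. CP190 regions with CLAMP stand at 4.26 and 3.81, whereas CLAMP regions with CP190 stand at 1.76 and 0.766.

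CP190 was called at the ends of most ribosomal protein genes, 78 of 92 (84.8%), against 43.2% of other genes (adjusted Fisher's exact p = 1.45e-15). RpL7A, RpS14a and RpL37A were among those with the highest ranks and among the 45 that were kept. Cell cycle and replication genes were bound in 23 of 28 cases (adjusted exact p = 0.000133), including stg, the Cdc25 phosphatase, CycB, a mitotic cyclin, Mcm7, a subunit of the replicative helicase, and dup, a replication licensing factor, all of them among the 10 that were kept. The dosage compensation genes were bound in 10 of 10 cases (adjusted exact p = 0.00071): roX1, roX2 and Sxl were kept, msl-2 was called in 1 dsCP190 library, and 6 genes lost every region. The bound share of insulator protein genes did not pass the test (14 of 23, adjusted exact p = 0.224). Of these 14 genes, 8 lost every region and 3, with pzg and su(Hw) among them, were kept. CTCF and pita were called in 1 dsCP190 library. Heat shock genes did not pass (10 of 19, adjusted exact p = 0.588), nor did ecdysone response genes (6 of 13, adjusted exact p = 1). Of the 10 heat shock genes, DnaJ-1 was kept, Hsp83 was called in 1 dsCP190 library, and 8, with Hsc70-4 and Hsp22 among them, were lost. Among the 6 ecdysone genes, EcR, ftz-f1 and Eip63E were kept, Hr39 was called in 1 dsCP190 library and 2 were lost. Hox complex genes did not pass (3 of 12, adjusted exact p = 0.431), nor did hemocyte markers (5 of 17, adjusted exact p = 0.439). Among the 5 hemocyte genes, srp, ush and Pvr were kept, and 2, with Hml among them, were called in 1 dsCP190 library. Markers of other cell types did not pass either: 4 of 14 neuronal genes (adjusted exact p = 0.439), 3 of 14 muscle genes (adjusted p = 0.224) and 4 of 12 germline genes (adjusted p = 0.622) were bound. None of 111 replication-dependent histone genes had a call (adjusted exact p = 5.09e-27), a value made uncertain by their near-identical copies. Without CP190 mock replicate 1 the insulator list also passed (adjusted Fisher's exact p = 0.0492). In all these tests the other genes include lncRNA genes, of which 9.85% had CP190, against 48.1% of protein-coding genes. This lowers the share among other genes and favours lists of protein-coding genes.

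Ribosomal protein genes lost every CP190 region in 18 of 78 cases (23.1%), against 50.8% of other bound genes (odds ratio 0.291, adjusted Fisher's exact p = 1.14e-05). Within quintiles of the strength of the gene's strongest region, an alternative chosen after the data were seen, the odds ratio was 0.495 with a 95% interval of 0.222 to 1.10, which includes 1. For the other lists the lost share did not pass the adjusted test, with 6 of 23 cell cycle genes (adjusted exact p = 0.119) and 0 of 5 hemocyte markers (adjusted p = 0.119) nearest to it.

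CLAMP was called at the ends of 41 of 92 ribosomal protein genes (44.6%), against 11.3% of other genes (adjusted Fisher's exact p = 1.58e-14), with RpS19a, RpS28a, RpL14 and RpL7 ranking first. None of the 41 was kept: 22, these 4 among them, were called in dsCP190 replicate 1 but not in replicate 2, and 19 were called in neither. Kept counts depend on strength. Of all CLAMP regions, replicate 2 retained 80.4% in the strongest quintile, 25.6% in the second and 2.87% in the middle one. Most of the 41 lay in quintiles 3 to 5, while RpS19a and RpS28a lay in quintile 1. Heat shock genes were bound in 11 of 19 cases (adjusted exact p = 8.52e-06): 3, with Hsp68 and Hsp27 among them, were kept, and 5 were lost. Hsp70Bb and Hsp70Bbb, near-identical copies with uncertain values, were called in 1 dsCP190 library. Hox complex genes were bound in 5 of 12 cases (adjusted exact p = 0.0237), and all 5 regions, among them those at Scr, lab, abd-A and Dfd, were kept. These 5 regions lay in quintiles 1 and 2, so gene class and strength were not separated here. Cell cycle genes were bound in 9 of 28 cases (adjusted exact p = 0.0124), and ecdysone response genes in 5 of 13 (adjusted p = 0.028). Of the 9 cell cycle genes, dup and dap were kept, 4, with stg and CycD among them, were called in 1 dsCP190 library, and 3 were lost. Of the 5 ecdysone genes, Hr39 was kept, Eip75B and Eip63E were called in 1 dsCP190 library, and 2, with Eip74EF among them, were lost. Insulator protein genes (5 of 23, adjusted exact p = 0.265), dosage compensation genes (3 of 10, adjusted p = 0.17, with Clamp kept, roX2 called in 1 dsCP190 library and Sxl lost), hemocyte markers (3 of 17, adjusted p = 0.58, with lz kept and srp and Nplp2 called in 1 dsCP190 library) and histone genes (7 of 111, adjusted p = 0.17) did not pass, nor did neuronal (2 of 14, adjusted p = 0.732), muscle (2 of 14, adjusted p = 0.732) and germline markers (1 of 12, adjusted p = 1). For no list did the share of genes that lost every CLAMP region pass the test against other bound genes, and the lowest adjusted Fisher's exact p was 0.46. For ribosomal protein genes the odds ratio of loss was 1.18, and 0.505 within strength quintiles, chosen after the data were seen, with a 95% interval of 0.236 to 1.08, which includes 1. Loss here means no call in either dsCP190 library. With a 200 bp window only the ribosomal and heat shock lists passed. With a 1000 bp window the ecdysone list passed beside them, without mock replicate 1 the Hox and ecdysone lists no longer passed, and the histone list passed as bound less often without mock replicate 1 and without mock replicate 2 (adjusted Fisher's exact p = 0.0222 and 0.0271). With regions called in either mock library, hemocyte markers passed as bound more often (adjusted Fisher's exact p = 0.0413), and the histone list passed as bound less often (adjusted Fisher's exact p = 0.00189).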

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

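Peaks on the Y chromosome, on unplaced sequences and on sequences assigned to X without a position lay outside the comparisons above. Every library held more than 3 of them, the limit used for flagging. CP190 lists held 10 and 15 such peaks in mock replicates 1 and 2, and 13 and 8 in dsCP190 replicates 1 and 2. CLAMP lists held 5 and 8 in mock and 6 and 9 in dsCP190 replicates 1 and 2. The CP190 lists placed 2 and 3 of these on Y in mock cells and 1 and 2 in dsCP190 cells, and CLAMP lists placed 0 there. The cells are labelled as female, so calls on Y are uncertain, and these small counts were not compared between antibodies.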

How the results depend on the processing

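The strata with gene ends, the choice of partner regions by their dsCP190 calls and the lost shares of gene lists within strength quintiles were tried after the data were seen. Under the alternatives fixed beforehand, 169 values counted as unchanged, 28 moved, 5 reversed, 3 passed and 5 no longer passed a threshold. Under those chosen afterwards, 9 were unchanged, 1 reversed and 2 no longer passed. Counts and peak ratios were unchanged within a fixed factor, and overlaps within the Wilson interval of the main value. Odds ratios were unchanged when their direction held and their interval still excluded, or still included, 1. A change of direction also counted as unchanged where both intervals included 1. With 50% of each peak shared, CLAMP odds ratios in dsCP190 replicate 2 went from 0.878 to 1.29 at gene ends. On X they went from 1.27 to 0.878. The cause was not tested for any change below. With a −log10 q of at least 10, the ratio of CP190 peak numbers was 0.221, the overlap of CLAMP with CP190 was 37.5% in mock and 13.1% in dsCP190 cells, and CLAMP retention by CP190 in dsCP190 replicate 2 had an odds ratio of 0.963 (0.795 with at least 3). With lists cut to equal length within each treatment the overlaps were 29.5% and 7.64%, so lengths still differed between mock and dsCP190 cells. With 50% of each peak shared they were 20.5% and 8.21%, and with summits within 100 bp 14.4% and 4.62%. With summits within 100 bp, CLAMP retention by CP190 in replicate 1 reversed to 0.856, and the X odds ratio for CLAMP in replicate 2 was 1.35. Without strata, the values were 1.08 for CLAMP by CP190 in replicate 2 (reversed), 0.916 and 0.843 for CLAMP at gene ends in replicates 1 and 2 (the first reversed), and 1.16 for CP190 on X in replicate 1. CLAMP by CP190 in replicate 2 was 0.810 with 10 strata, 0.791 with gene ends in the strata, and 1.46 (reversed) with partners called in both dsCP190 libraries. That last choice takes the partner from treated cells, as the outcome is, so it does not bear on the comparison. CLAMP passed for 2 lists with a 200 bp window and 3 with 1000 bp, against 5. The CP190 loss of ribosomal protein genes had an odds ratio of 0.495 within strength quintiles.

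Leaving out each replicate gave CLAMP peak ratios from 0.201 to 0.549 and 1466 to 2849 lost CLAMP regions. Higher lost counts follow from the looser definition with fewer libraries. Overlaps ran from 41.8% to 44.1% in mock and from 15.6% to 27.6% in dsCP190 cells. Odds ratios for CLAMP by CP190 in dsCP190 replicate 2 ran from 0.753 to 0.870, and 3 to 5 lists passed for CLAMP. CP190 by CLAMP stayed above 1 in both libraries in every alternative with partners from mock cells, from 2.58 to 4.48 in replicate 1 and from 1.92 to 3.99 in replicate 2, each taken alone. Replicate numbers are shared by the groups, but nothing in the labels says that they pair the samples. With the replicate block, the peak ratios were 0.324 for CP190 and 0.332 for CLAMP, CP190 by CLAMP was 4.07, CP190 at gene ends 2.38, and X 0.994 for CP190 and 1.03 for CLAMP; CLAMP by CP190 was 1.34 (95% interval 1.17 to 1.54) and CLAMP at gene ends 1.32 (1.14 to 1.53). The block gives 1 odds ratio over both libraries, and these intervals exclude 1, in the direction of dsCP190 replicate 1 and reversed against replicate 2. The motif windows and flanks were not run, since they need a genome sequence, which was not used here. The CLAMP dsCP190 libraries had median backgrounds of 7.97 and 8.19 fragments at their peaks, which limits what weak regions can show.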

Other observations

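The tests of gene-end location and of immunoprecipitation yield, and the comparisons of X shares and of noncoding genes, were chosen after the results were seen. CLAMP lists held more of their peaks on X than CP190 lists in all libraries. The X share was 27.0% ± 1.64 (SD, n = 4) for CLAMP, from 25.7 to 29.3, and 19.3% ± 0.699 (SD, n = 4) for CP190, from 18.6 to 20.2 (two-sided exact permutation p = 0.0286, the smallest possible, over libraries of both treatments). The libraries of an antibody span both treatments and call many of the same regions. They are not independent, and the SD holds treatment as well as replicate spread. X holds 15.8% of protein-coding genes and 17.6% of the arm length.

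Genes of tRNAs and lncRNAs were bound less often than protein-coding genes. CP190 was called at the ends of 48.1% of 13922 protein-coding genes, 20.3% of 290 tRNA genes (adjusted Fisher's exact p = 7.48e-22) and 9.85% of 1959 lncRNA genes (adjusted p = 7.55e-261). CLAMP was called at 11.9% of protein-coding, 6.21% of tRNA (adjusted exact p = 0.00204) and 8.42% of lncRNA genes (adjusted p = 4.51e-06). For snRNA genes, 13 of 32 had CP190 (adjusted exact p = 0.48) and 2 of 32 had CLAMP (adjusted p = 0.461). Many tRNA and snRNA genes have near-identical copies, so their values are uncertain. CP190 was called at 8.92% of snoRNA genes, 7.69% of miRNA genes and 13.9% of pseudogenes, and CLAMP at 4.46%, 5.77% and 2.86%. The windows at the ends of a short gene overlap, so it offers less sequence in which a summit can count. Gene length was not adjusted for, so low shares of short genes cannot be read as avoidance.

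Fewer CP190 peaks were called after dsCP190. Thinning the mock pileups to the depth of the dsCP190 libraries left at least 99.1% of regions above the threshold. The observed share fell short of that by at least 75.2 percentage points in replicate 1 and 59.1 in replicate 2, against a gap of at most 6.77 between the mock libraries, which argues against lower depth as the whole explanation. Between the dsCP190 libraries the gap was 13.9 in one direction and 42.4 in the other, both under 59.1. The knockdown stays open, as does a difference in precipitation yield that goes with treatment, since the design does not separate them.

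Fewer CLAMP peaks were called after dsCP190, and the dsCP190 libraries were 2.24 to 2.84 times shallower than the mock libraries. Thinning predicted that 88.4% or more of regions would be retained in replicate 1 and 80.2% or more in replicate 2. The observed shares fell short by at least 28.5 and 58.2 percentage points, more than the 16.3 seen between mock libraries, which argues against depth alone. A difference in immunoprecipitation yield between libraries of 1 treatment could account for the pattern: at nearly equal depth, dsCP190 replicate 2 fell 63.6 percentage points short of what replicate 1 predicted, as large a gap as either replicate had to mock, while replicate 1 fell only 1.41 short of what replicate 2 predicted. An effect of the knockdown on CLAMP stays open as well, and 2 replicates do not separate it from yield or depth.

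CP190 calls were kept more often where CLAMP had been called. Shared gene-end location was argued against as the whole explanation: with gene ends added to the strata, the smaller odds ratio was 3.33, with a 95% interval starting at 2.79. Non-specific signal at CLAMP regions may contribute, since CP190 peaks that appeared only after dsCP190 lay at CLAMP regions in 129 of 186 cases in replicate 1 and 50 of 63 in replicate 2, against 127 of 782 regions called in 1 mock library only. The smaller odds ratio was 11.7, with a 95% interval starting at 8.10, and 23 of the 24 gained regions overlapped a CLAMP region. Retention of CP190 itself at these regions after the knockdown stays open and was not tested.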
